A study of Acetivibrio thermocellus ATCC 27405 with 12 samples.

How the data were processed

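The samples were total RNA from wild-type batch cultures of Clostridium thermocellum ATCC 27405 (also called Acetivibrio thermocellus), turned into double-stranded cDNA, labelled with Cy3 and hybridised to NimbleGen tiling arrays, per the labels. Each deposited scanner table holds 686926 probes of 1 array with their raw intensity, read with NimbleScan 2.4.27, per the file headers. These intensity values were neither background-corrected nor scaled between arrays. The authors' deposited value table holds log2 values for 631460 probes of the same 12 arrays. It correlated with the log2 scanner intensity with r between 0.902 and 0.997 per array, so its columns and direction are known, while the normalization behind it is not given in the sources used here. It served as an alternative. All of its sample columns matched a sample.

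The array design in the scanner tables gives 631786 genome probes, 315893 for each strand at a median spacing of 12 bases, in 4769 regions from base 104 to base 3843276 of sequence CP000568, beside 50000 random control probes and 5140 gap probes. Coordinates are 1-based as in the files. No annotation was used here, and the files do not pair regions with gene names or locus tags. The 30 gene lists and the named genes fixed before the data were examined could therefore not be applied, and no gene set test was run. Regions were sorted by their layout. Runs of touching regions alternate between a gene and the space beside it, and each run was anchored where a neighbour overlapped or lay under 90 bases away. This gave 2950 gene-like regions, 1617 spacers and 202 unclear regions. Region length was not used for the sorting; it was a multiple of 3 in 100% of gene-like regions and in 34.4% of spacers. Spacers can hold RNA genes. The 652 spots of 326 probe names set in 2 regions were left out, and regions under 5 probes were not tested, which left 2947 gene-like regions and 1611 spacers.

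Intensities were corrected with normexp (offset 50), quantile normalised over all spots and set on the log2 scale in R 4.3.3 with limma 3.58.1. A region's value was the median over its probes of both strands. Arrays of the same group and F number were averaged, since the series design states 2 biological replicates per condition while ethanol at 60 min has 4 arrays with 2 F numbers. The labels do not say what the F number stands for; it was taken as the replicate number. The 9 replicates were fitted as 5 groups with lmFit and eBayes (trend), with 4 residual degrees of freedom and Benjamini-Hochberg adjustment over the gene-like regions, or over the spacers for spacers, at 0.05. The number of arrays limits the precision. Control cultures carry F numbers 1 and 3 and ethanol cultures 2 and 4. The 12 arrays lay on 5 slides scanned on 3 days. A region was above background on an array if its median raw intensity exceeded the 95th percentile of the random probes. Where a region was not above background on any array of the dimmer group, the fold is a lower bound against the lowest normalised value of a region above background on each array, or its own value if higher.

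The regions to be named were, by a rule set before the data were examined, the 10 largest rises and 10 largest falls at 30 and at 60 min and the 6 largest each way from 30 to 120 min, among those past the threshold with replicates that did not overlap, and the 5 smallest p for the interaction and for spacers. Without names, 2 per direction are printed and the others are summarised. Alternatives covered the background correction, the normalization, the probe summary, the strand, a filter on dim regions, the authors' values, the handling of repeated arrays, the slide, the replicate number, each replicate left out, the fit and the thresholds.

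The fitting functions were tested on simulated data with the spread of the real replicates, with 200 of 2947 regions changed. For ethanol against control at 30 min, 33 of 100 changes of 1 on the log2 scale and 83 of 100 changes of 2 were recovered, with 8 false calls. At 60 min it was 58 and 96 of 100, with 8 false calls. The simulated errors were independent between regions and had the same spread in all groups. False calls under unequal spread, or where neighbouring regions vary together, were not tested.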

Results

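The series followed the transcriptome of wild-type Clostridium thermocellum ATCC 27405, an anaerobic thermophilic bacterium that degrades cellulose and ferments it to ethanol, after ethanol was added to batch cultures in bioreactors. Cultures with 0.5% v/v ethanol (3.95 g/L) were sampled at 30, 60 and 120 min and cultures without ethanol at 30 and 60 min. Labelled double-stranded cDNA was hybridised to 12 genome tiling arrays. The arrays formed 9 replicates, which were 1 of control at 30 min (2 arrays of the same F number), 2 of control at 60 min, 2 of ethanol at 30 min, 2 of ethanol at 60 min (2 arrays each) and 2 of ethanol at 120 min. Values were compared for 2947 gene-like regions and 1611 spacers between them, with coordinates on sequence CP000568. The files do not pair regions with gene names, so regions are given by their start and end, and at most 2 that rose and 2 that fell are named for each comparison.

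The arrays differed in signal over background. The median genome probe was 9.38 and 3.68 times as bright as the median random control probe on the control arrays at 30 min, and 5.66 and 3.18 times on the ethanol arrays at 30 min. It was 1.43 and 1.19 times as bright on the control arrays at 60 min, between 1.32 and 1.80 times on the ethanol arrays at 60 min, and 5.92 and 5.79 times on the ethanol arrays at 120 min. Gene-like regions above the 95th percentile of the random probes made up 60.9% on the dimmest array, control at 60 min with F number 1, and 96.8% on the array with the highest share, ethanol at 30 min with F number 2. All arrays of 60 min were scanned on other days than those of 30 and 120 min, so differences between 60 min and the other times cannot be told apart from the scan day. Control and ethanol cultures of 30 min were scanned on the same day. At 60 min the control with F number 1 was alone on its slide and its scan day, while the other control shared a day with all ethanol arrays of 60 min.

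**Figure D1:**
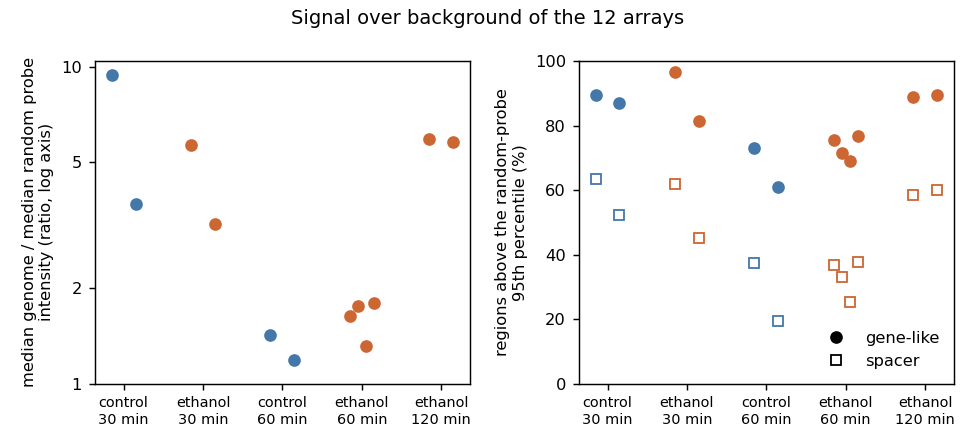
Each point is 1 array; the left panel shows the ratio of median genome probe to median random probe intensity on a log axis, and the right panel the percentage of gene-like regions (filled circles) and spacers (open squares) above the random-probe 95th percentile, with controls in blue and ethanol in orange. The ratio was 1.19 on the dimmest control array at 60 min and 9.38 on the brightest control array at 30 min.

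The first question was which transcripts had changed 30 min after ethanol addition. The region from 239756 to 240847 had a normalised log2 intensity of 8.36 in the control replicate and 11.69 ± 0.37 (SD, n = 2) with ethanol, a 10.1-fold higher signal (log2 change 3.33, SE 0.28, limma adjusted p = 0.00152). The region from 3656550 to 3657392 rose from 8.71 to 11.74 ± 0.13 (SD, n = 2), which was 8.21-fold. Among the regions that fell, the log2 intensity of the one from 3442610 to 3443893 was 12.71 in the control and 10.04 ± 0.43 (SD, n = 2) with ethanol, a log2 change of -2.67 (SE 0.53, limma adjusted p = 0.0219), and that from 2605210 to 2605497 changed by -2.63 (SE 0.31, limma adjusted p = 0.00318). In all, 260 of 2947 gene-like regions passed an adjusted p of 0.05, 131 higher and 129 lower, and 244 of them changed at least 2-fold. The estimates of the 10 largest rises lay between 5.03-fold and 10.1-fold and those of the 10 largest falls between 5.27-fold and 6.35-fold. For 1 of the rises, from 1864928 to 1867033, no control array was above background, so only a rise of at least 4.93-fold holds. The control group had 1 replicate here, so its spread was taken from the other groups through the shared fit. Within the slide that held both groups, with 1 control array beside 2 ethanol arrays and the spread taken from pairs of ethanol arrays, 778 regions were called, and the first region named changed by 3.31 there; without the ethanol replicate with F number 2 or 4 the count was 132 or 9, and without the latter the region from 3442610 to 3443893 no longer passed (limma adjusted p = 0.177). Scaling each array to a common median gave 509 higher and 249 lower regions in place of 131 and 129, with the median of all regions at 0.17 on the log2 scale. The spread is shared between groups, so replicates of other times moved the count too: it was 938 or 933 without the control of 60 min with F number 1 or 3, 100 or 99 without the ethanol replicate of 60 min with F number 2 or 4, and 80 without either of 120 min. With only the second or only the first control array it was 93 or 584.

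At 60 min the same question was asked of 2 control and 2 ethanol replicates. The region from 3657482 to 3658714 had a log2 intensity of 8.63 ± 0.12 (SD, n = 2) in the controls and 12.19 ± 0.12 (SD, n = 2) with ethanol, 11.8-fold higher (log2 change 3.56, SE 0.24, limma adjusted p = 0.000135). Its neighbour from 3656550 to 3657392 rose 11.4-fold. Both regions were above background on only 1 of the 2 control arrays, so these folds rest in part on a control value below background. The region from 3445961 to 3446074 changed by -2.73 (SE 0.35, limma adjusted p = 0.00177), from 11.31 ± 0.28 to 8.58 ± 0.59 (SD, n = 2 each). The region from 912459 to 913067 also changed by -2.73 (limma adjusted p = 0.00177), and in the authors' deposited values by -1.26 (limma adjusted p = 0.0762). Of the 4 ethanol arrays, the region that starts at 3445961 was above background on 3 and that at 912459 on 2. These falls thus rest in part on ethanol values below background. At this time 510 gene-like regions passed the threshold, 277 higher and 233 lower, of which 310 changed at least 2-fold. Of the 10 largest rises, 4 were in regions not above background on either control array, so that only a lower bound holds; the bounds were 7.16-fold for the region from 239756 to 240847 and 4.06-fold, 4.03-fold and 3.03-fold for those that start at 1864928, 2154102 and 2157057. Within the slide that held both groups, 1098 regions were called, again from 1 control array beside 2 ethanol arrays and with the spread taken from pairs of ethanol arrays, so this count does not hold the spread between controls. The 2 control replicates differed from each other (SD of the difference 0.70 on the log2 scale) more than the ethanol pairs at 30 and 120 min (0.33 and 0.24), and without the control with F number 1 or the control with F number 3 the count was 1065 or 1480. It was 156 or 92 without the ethanol replicate of 60 min with F number 2 or 4, and 309 or 310 without that of 120 min with F number 2 or 4. The authors' deposited values gave 85 higher and 52 lower, and median scaling 279 higher and 117 lower.

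Across the 2947 gene-like regions the changes at 30 and 60 min correlated with r = 0.79, where regions are not independent replicates. Both lists held 113 regions that were higher and 108 that were lower at both times, against 12.3 and 10.2 for independent lists, and 0 regions went opposite ways. Both comparisons took each region's spread from the same fit, so the lists are not fully independent even without a shared response. The 2 comparisons shared no array, though the ethanol cultures carry F numbers 2 and 4 at both times and a control with F number 1 is in both; F number 3 is at 60 min only. All regions called at 30 min had the same direction at 60 min, and 97.6% of those called at 60 min had the same direction at 30 min. The test of a difference between the responses called 0 regions in limma, with 63 regions at an unadjusted p under 0.05 and a smallest adjusted p of 0.877. The region from 541944 to 542189 had the smallest p, with a response larger by 1.85 at 60 min (SE 0.39). The same test called 359 regions after median scaling, 13 with a larger and 346 with a smaller value at 60 min, 38 with the slide as a fixed block and 786 without the control at 60 min with F number 3.

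**Figure D2:**
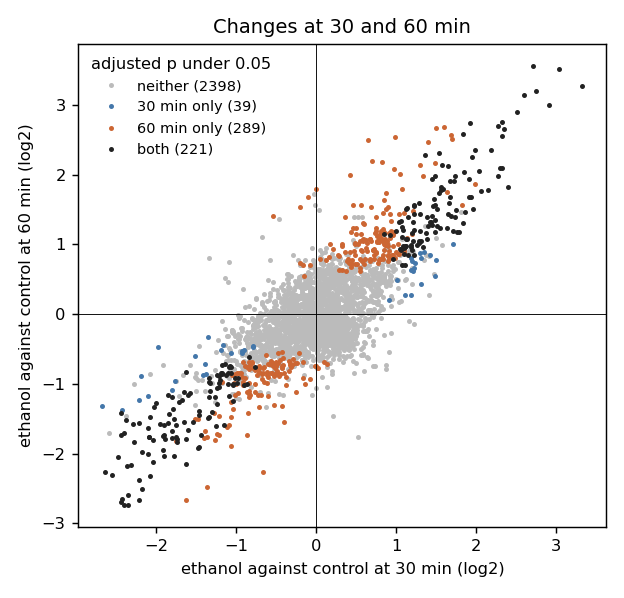
Each point is a gene-like region, with its log2 change of ethanol against control at 30 min on the horizontal axis and at 60 min on the vertical axis, coloured by the time at which its adjusted p was under 0.05. The 221 regions called at both times lie in the 2 quadrants where the signs are the same.

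Over both times together, 785 gene-like regions differed with ethanol, 388 higher and 397 lower, and 329 of them by at least 2-fold. The count was 1381 or 1335 without the control of 60 min with F number 1 or 3, 478 without the ethanol replicate of 30 min with F number 4, 504 or 476 without the ethanol replicate of 60 min with F number 2 or 4, and 1287 with the slide as a fixed block. The ethanol cultures carry F numbers 2 and 4 at both times, and a control with F number 1 is at both. If an F number stands for 1 bioreactor, its samples at the 2 times are not independent, though the fit takes them so. This holds for all results over both times. Changed regions lay next to each other. Counting neighbouring gene-like regions that changed the same way, 26 runs held at least 5 regions, 14 of them higher and 12 lower, and these held 222 regions. The longest run had 35 regions, and in 1000 shuffles of the region order the longest had 7. The runs described here were chosen after their values were seen. The longest run reached from 3433095 to 3452463, over 19.4 kb, and its 35 regions fell on average by 1.75 on the log2 scale (range -2.54 to -0.64), with means of -1.90 at 30 min and -1.60 at 60 min. Its mean log2 intensity was 12.2 in the control at 30 min and 12.4 and 11.7 in the controls at 60 min, against 10.6 and 10.1 with ethanol at 30 min and 10.8 and 10.2 at 60 min. A run of 12 regions from 3537193 to 3547970 changed by a mean of -1.52 and a run of 6 regions from 912459 to 917716 by -2.22. In the latter, the regions that start at 912459 and 913436 were above background on only 2 ethanol arrays of 60 min. Among the runs that rose, 14 regions from 2145148 to 2158316 had a mean change of 1.72, 10 regions from 1887838 to 1896849 of 1.92, and 5 regions from 237071 to 244034 of 2.66. Their members that start at 2154102, 2157057 and 239756 were above background on neither control array of 60 min. The member that starts at 1891537 was above it on only 1. These mean changes thus rest in part on control values below background. The run of 12 regions from 574145 to 587090, with a mean change of -0.997, differed by 1.55 between the 2 control arrays of 30 min, which carried the same F number on 2 slides. This difference was over 0.5 of the mean change in 9 of the 26 runs, among them the runs that start at 2989961 (1.46 against a mean change of -1.51), 2648775 (1.20 against -1.68) and 1930261 (-1.05 against 1.5). Within the slide of 30 min the run that starts at 574145 changed by -0.15.

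**Figure D3:**
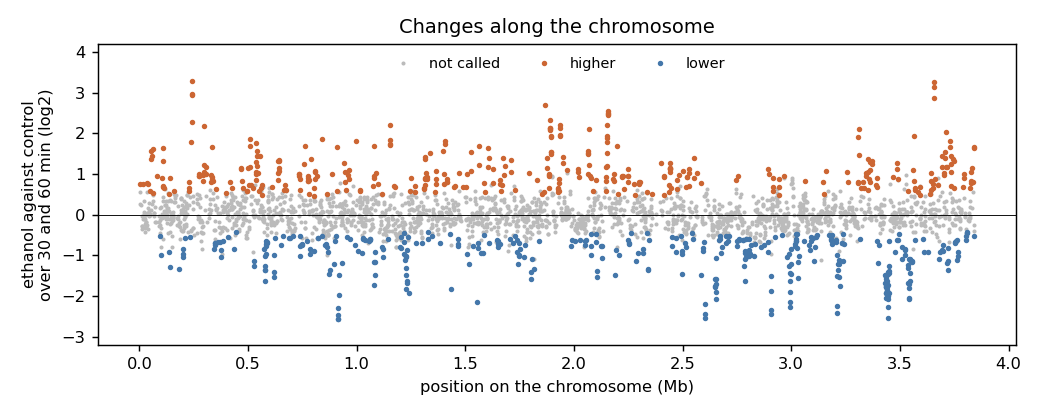
Each point is a gene-like region at its position on the chromosome in Mb, with its log2 change of ethanol against control over 30 and 60 min on the vertical axis; orange points were higher and blue points lower at an adjusted p under 0.05, and grey points were not called. The called points form vertical groups where neighbouring regions changed together, among them the 35 regions that start at 3433095.

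**Figure D4:**
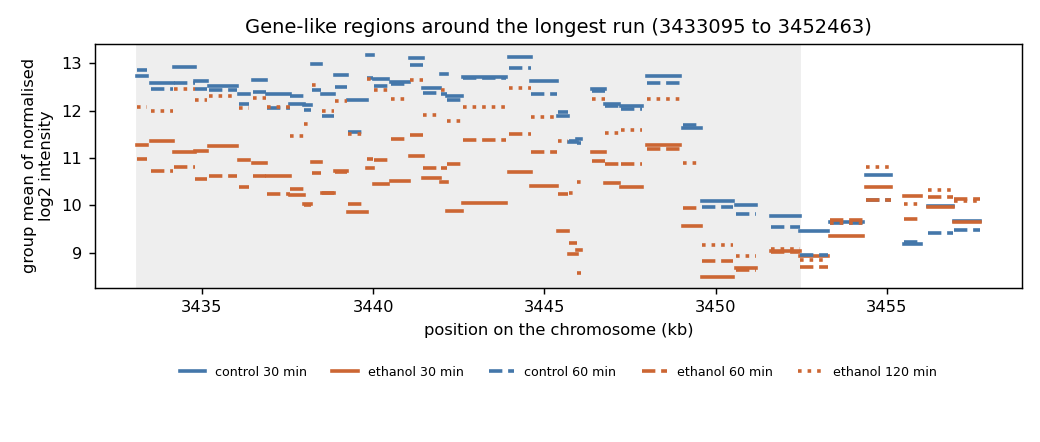
Each horizontal bar is a gene-like region drawn from its start to its end in kb, at the group mean of its normalised log2 intensity, with controls in blue and ethanol in orange, and the line style giving the time; the run is shaded in grey. The mean over the 35 regions was 12.2 in the control at 30 min, 10.6 and 10.1 in the ethanol replicates at 30 min, and 11.8 and 11.6 in those at 120 min. The rise of 1.35 from 30 to 120 min was 0.80 with the slide as a fixed block, which corrects through 1 control array on each slide.

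The ethanol cultures were then compared with each other over time. F numbers 2 and 4 occur at all 3 times, so if an F number stands for 1 bioreactor, these samples come from the same 2 cultures and are not independent. With the F number as a fixed block, or only the compared groups in the fit, all 3 main counts were larger, as given under the processing. From 30 to 60 min limma called 0 gene-like regions, with 373 at an unadjusted p under 0.05, while median scaling gave 614, 534 higher and 80 lower, and the fit without either control replicate of 60 min 430 or 433. From 30 to 120 min it called 12, with 11 higher and 1 lower. The region from 3004536 to 3005255 had a log2 intensity of 9.64 ± 0.99 (SD, n = 2) at 30 min and 12.57 ± 0.29 (SD, n = 2) at 120 min (log2 change 2.93, SE 0.46, limma adjusted p = 0.0336), and that from 3006426 to 3008225 rose by 2.85 (SE 0.45). The region that fell, from 1153900 to 1154358, changed by -2.14 (SE 0.26, limma adjusted p = 0.0155). It had been 2.33 higher with ethanol than in the control at 30 min on the log2 scale. The 12 regions kept their direction with the slide as a fixed block and 11 of them passed the threshold there, though the sizes moved: the 2 named rises were 5.08 and 4.79 in that fit. Ethanol at 30 and at 120 min lay on different slides, so this block corrects through 1 control array on each, both with F number 1. These 2 arrays differed with an SD of 0.52, against 0.33 and 0.24 between the ethanol replicates at 30 and 120 min. None of the 3 named regions passed without either ethanol replicate of 30 min or of 120 min, with limma adjusted p between 0.0515 and 0.396, nor with reverse-strand probes only (limma adjusted p from 0.0520 to 0.0642). From 60 to 120 min 6 regions were called, 4 higher and 2 lower. Without the control of 60 min with F number 1 or 3 the counts were 510 or 502 from 30 to 120 min and 536 or 540 from 60 to 120 min. The count from 30 to 120 min was 0 without either ethanol replicate of 30 min or that of 120 min with F number 4, and 7 without that of 120 min with F number 2. The count from 60 to 120 min was 0 without either ethanol replicate of 60 min or that of 120 min with F number 4, and 1 without either of 30 min. The direction of these counts moved with the normalization. From 30 to 120 min, median scaling gave 106 higher and 464 lower, cyclic loess 34 and 51, and the authors' deposited values 103 and 92; from 60 to 120 min, median scaling gave 127 higher and 850 lower and cyclic loess 6 and 8.

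The control cultures were compared at 60 against 30 min, where limma called 0 gene-like regions with 215 at an unadjusted p under 0.05, and 941 after median scaling, of which 843 were higher. Without the control of 60 min with F number 3 or 1 the count was 813 or 54. In the same comparison 151 spacers were called, 144 of them higher, with no ethanol in either group. The raw intensities went the other way: 832 spacers were above background on both control arrays at 30 min and 298 at 60 min. The arrays of 60 min were dimmer, so this rise cannot be told apart from the normalization of dim arrays. The files used here hold no control of 120 min, so ethanol at 120 min was set against control at 60 min, a comparison that mixes ethanol, time and scan day. It called 665 gene-like regions, 382 higher and 283 lower, and with median scaling 567 higher and 997 lower, and with cyclic loess 232 higher and 289 lower. The count was 1345 or 1513 without the control of 60 min with F number 1 or 3, 137 or 111 without the ethanol replicate of 120 min with F number 2 or 4, and 388 without either ethanol replicate of 60 min. Among the spacers it called 720, 132 higher and 588 lower, so the balance was the other way. Here too the raw direction was opposite, with 927 spacers above background in ethanol at 120 min and 298 in control at 60 min.

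Signal between the gene-like regions was compared with the random probes. In all, 269 of 1611 spacers (16.7%) exceeded the random-probe 95th percentile on all 12 arrays, beside 1681 of 2947 gene-like regions (57.0%). By group, 832 spacers were above it on both control arrays at 30 min, 298 at 60 min, 723 on both ethanol arrays at 30 min, 400 on the ethanol arrays at 60 min and 927 at 120 min. In the same order, the share of gene-like regions was 86.2%, 59.5%, 81.5%, 68.4% and 88.4%. Array brightness differed between groups, and 4 arrays had to pass in ethanol at 60 min but 2 in each other group. These counts therefore cannot be read as changes in spacer transcription. With ethanol over both times 187 spacers changed, 64 higher and 123 lower, beside 8 at 30 min and 65 at 60 min. The count was 597 or 445 without the control of 60 min with F number 3 or 1, 62 without the ethanol replicate of 30 min with F number 4, 63 or 46 without the ethanol replicate of 60 min with F number 2 or 4, 116 or 114 without the ethanol replicate of 120 min with F number 2 or 4, and 117 or 300 without the first or the second control array of 30 min. The authors' deposited values gave 343, and probes at least 100 bases from a gene-like region 44, over fewer spacers. Over all spacers the median change was -0.03 at 30 min and -0.18 at 60 min, where the control arrays were on average dimmer. The excess of falls among the 187 therefore cannot be told apart from the normalization of dim arrays. The spacer from 3658715 to 3658824 rose by 2.70 (SE 0.25, limma adjusted p = 0.00106) and lies between gene-like regions that also rose. It was above background on no control array of 60 min. The spacer from 2156919 to 2157056 had an estimated rise of 2.07 but was above background on no control array of either time. That estimate rests on control values below background, and no lower bound was computed for it. The spacers from 3433407 to 3433508 and from 1230887 to 1231003 changed by -2.12 and -1.84. A neighbouring gene-like region had changed the same way for 163 of the 187 spacers (87.2%), while 41.0% of all spacers had a changed neighbour. Measured only by probes at least 100 bases from a gene-like region, the changes of 837 spacers correlated with the mean change of the neighbours with r = 0.62 across spacers.

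The 2 strands were compared. The correlation of region values from forward-strand and reverse-strand probes across gene-like regions had a median of 0.97 over the 12 arrays and was lowest, at 0.86, on the control array at 60 min with F number 1, and the changes with ethanol correlated with r = 0.97 at 30 min and 0.92 at 60 min. The labelled material was double-stranded, so strand was not resolved.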

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

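The tests of array brightness, of the slide at 30 and 60 min, of selection on the data, of the slide in regions called higher, of the untiled spaces, of dim arrays and of the gap probe set were chosen after the results were seen.

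One array stood apart from the others of its group. The agreement between strands on the 4 ethanol arrays at 60 min was 0.92 on the second array with F number 4 and 0.97 on each of the others, and the gap to the nearest array was 0.940 of the range, above the critical value of Dixon's test for 4 samples. Of 15 values tested this was the only 1, and chance flags about 5% of groups. The array was also the dimmest of its group.

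A signal appeared in the gap probes, a set of 124 regions outside the tiled comparisons. Over 30 and 60 min 36 of them were higher with ethanol and 1 was lower in limma. At 30 min alone none was called, and at 60 min 20 were, all of them higher. Repeated elements were a candidate explanation, since 59 of 104 untiled spaces have 1 of 6 recurring lengths. The values argue against repeats in these spaces as the source, while repeats inside tiled regions were not tested. Of the 36, only 2 lay over an untiled space, as did 28 of all 124 gap regions. The median change over such spaces was lower than elsewhere (difference -0.14 on the log2 scale). None of the 6 recurring lengths had a median rise over 0.5 at both times. The length of 948 bases, with 2 gap regions, rose by 0.30 at 30 min and 0.92 at 60 min, and neither region was called over both times. A bias of this probe set as the whole cause is argued against by the tiled probes around the 20 gap regions called higher at 60 min, which lie in 11 tiled regions: at 30 min, on other arrays, the tiled change had a median of 1.04 (quartiles 0.40 and 1.5) and was positive for all 20. A bias that adds to the rise stays open, since the gap probes of the 20 exceeded the tiled ones at 30 min by a median of 0.23 (quartiles -0.06 and 0.67). A larger difference of 0.43 in the 36 regions carries their selection for the rise and decides nothing. Dim arrays stay open too, with a median change of all gap regions of 0.44 at 30 min.

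The ethanol response was seen at both times. The changes at 30 and 60 min correlated with r = 0.79, while the controls were on average brighter than the ethanol arrays at 30 min and dimmer at 60 min. The order at 30 min rests on 1 control array, with genome to random probe ratios of 9.38 and 3.68 against 5.66 and 3.18. Gene-like regions above background there made up 89.5% and 86.9% in the control and 96.8% and 81.5% with ethanol. The correlation argues against array brightness as the whole cause only if that order holds, so brightness stays open. The slide is argued against by regions called at 1 time and measured at the other, within the slide that held both groups and so on other arrays: 100% of those called at 30 min and 95.9% of those called at 60 min kept their direction there. With no F number shared between the 2 times, the lower correlation was 0.84, which argues against differences between single cultures. The 18 splits of the replicates within each time are too few for a share under 0.05; the real split gave 785 regions and the highest other 0. Any property shared by both control F numbers and not by the ethanol ones stays open, beside ethanol itself.

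Regions called at 60 min appeared to move back toward the control at 120 min. Those called lower had a median change of 0.22 from 30 to 120 min and those called higher of -0.15, a difference of 0.36 that selection of extreme values does not produce, because the comparisons share no array. The slide stays open. The difference between the 2 slides was taken from 1 control array of 30 min on each. After subtracting it, regions called lower exceeded the uncalled ones by 0.038. Uncalled regions minus those called higher gave -0.26, which is away from the control. The control array on the other slide correlated better with the 120 min arrays (r = 0.94 and 0.93) than the one on their own slide (0.90 and 0.89). The difference thus holds more than the slide, and the subtraction cannot decide. The return is therefore not established for the called regions as a set.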

How the results depend on the processing

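The setting without the 2 dimmest arrays, and spacer changes measured only away from gene-like regions, were chosen after seeing the data. Counts are of gene-like regions unless spacers are named, in the order in which the comparisons are listed. Over both times, ethanol against control gave 785 regions and stayed within 1.5 times of this under every change of background correction, normalization, probe summary, strand and dim filter and under the authors' values, which called 938 and shared 730. The run that starts at 3433095 kept between 32 and 35 called regions in all fits run. The median genome probe was between 1.19 and 1.80 times as bright as the median random probe on the arrays of 60 min, which limits what these show for weak regions.

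Median scaling gave 758 regions at 30 min, 359 for the interaction, 614, 570 and 977 for ethanol at 60 against 30, 120 against 30 and 120 against 60 min, 941 for the controls and 1564 for ethanol at 120 min against control at 60 min. It shifted the median region by up to -0.26. Cyclic loess gave 568 at 30 min, 248 at 60 min, 85 and 14 for ethanol at 120 against 30 and 120 against 60 min, and 1 for the controls. The authors' values gave 800 at 30 min, 137 at 60 min, 3, 195 and 11 for the ethanol cultures over time, 2 for the controls, 435 for ethanol at 120 min against control at 60 min and 343 spacers. Median polish and eBayes without trend gave 14 and 12 for ethanol at 120 against 60 min. Reverse-strand probes gave 4 for ethanol at 120 against 30 min and 123 spacers.

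With 12 separate arrays the counts were 678 at 30 min, 876 at 60 min and 73, 72 and 234 for the ethanol cultures over time. With group and F number as a random block they were 426 at 30 min and 3, 31 and 65. With the slide as a fixed block they were 778, 1098, 1287 over both times, 38 for the interaction and 197 for ethanol at 120 against 30 min; as a random block 806, 1028, 1273, 1, 29 and, at 120 against 60 min, 3. Within the slide they were 778 and 1098. With only the compared groups in the fit they were 717, 136, then 329, 321 and 926 for the ethanol cultures over time, and 158 for ethanol at 120 min against control at 60 min. At least 2-fold change left 310 at 60 min, 329 over both times and 334 for ethanol at 120 min against control at 60 min. An adjusted p under 0.01 left 38, 175 and 428 for ethanol against control, 0 and 1 for ethanol at 120 against 30 and 60 min, and 211. The cause of these differences was not tested.

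Same-numbered ethanol replicates deviated together with r of 0.03, 0.07 and 0.17, so the numbers were not taken as pairs. A random replicate block gave 41 and 19 regions for ethanol at 120 against 30 and 60 min, and a fixed replicate block among the ethanol cultures 463, 566 and 565.

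Leaving out 1 replicate or array gave between 9 and 938 regions at 30 min, 92 and 1480 at 60 min, 476 and 1381 over both times, 0 and 786 for the interaction, 0 and 433, 0 and 510, and 0 and 540 for the ethanol cultures over time, 0 and 813 for the controls, 111 and 1513 for ethanol at 120 min against control at 60 min and 46 and 597 spacers. The high values came without 1 of the 2 control replicates of 60 min, whose difference was the largest between replicates of a group. For the interaction and the controls this was the one with F number 3, and for the other comparisons either raised the count. A replicate left alone is assumed to vary like the other groups. With only the second or only the first control array of 30 min, 93 or 584 regions were called at 30 min and 117 or 300 spacers over both times. Without the 2 dimmest arrays the counts were 913, 1072 and 1368 for ethanol against control, 450, 440 and 532 for the ethanol cultures over time, 3 for the controls, 1335 for ethanol at 120 min against control at 60 min and 429 spacers.

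Spacers with signal fell to 477, 97, 402 and 176 for control and ethanol at 30 and 60 min at the 99th percentile, and to 329, 124, 273, 146 and, at 120 min, 375 with probes at least 100 bases from a gene-like region, where 44 spacers changed over fewer spacers tested. Leaving out 1 array gave between 312 and 601 spacers with signal for control at 60 min. Gene set alternatives were not run, since no region has a name here.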

Other observations

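The 2 brightest gene-like regions in the controls did not pass the threshold. The SDs given here count replicates of both times, so F numbers recur among them. The region from 2345038 to 2345601 had a mean log2 intensity of 14.0 ± 0.66 (SD, n = 3) in the controls of 30 and 60 min and 13.9 ± 0.45 (SD, n = 4) with ethanol, and its neighbour from 2343495 to 2345024 had 13.7 and 13.5 (limma adjusted p = 0.837 and 0.998 over both times); both were chosen after their values were seen.

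Regions that were called from 30 to 120 min with ethanol clustered in 2 stretches, chosen after their values were seen. Those from 2997875 to 3010860 held 6 of the 12, and 3 neighbouring regions from 3301150 to 3304983 rose by between 2.06 and 2.75.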
